A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

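The 24 samples were 3 cultures of each of 8 groups: the reference strain, snf1Δ, tor1Δ and snf1Δtor1Δ, each under glucose limitation (C-lim) and under ammonia limitation (N-lim). Per the labels' protocols, the cultures were aerobic chemostats in bioreactors of 1.2 L with a working volume of 0.5 L, with 10 g/L glucose in the C-lim medium and 1 g/L ammonium sulfate in the N-lim medium, and were sampled at steady state. RNA was extracted from the frozen cells with a Qiagen kit, labelled with biotin and hybridized to 1 Affymetrix yeast array per culture, per the labels' protocols. Groups were taken from the sample titles and genotype labels. The titles carry a number per culture, used below as the replicate number.

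The deposited table holds log2 values, made by the authors with RMA and affy per the submitters' processing notes. Versions, and the set of arrays over which the authors normalized, are not given in the sources used here. Everything else was computed from these log2 values. The arrays' raw files were not used here.

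The table holds 5716 probe sets, of which 5498 were paired with 1 gene by the platform table and 0 with several. For 47 genes with several probe sets the brightest was used, which left 5449 genes, and 12 gene symbols were updated from the RefSeq table of assembly R64. The other 218 probe sets are not in the platform table and were kept out of the gene tests. No control probe sets and no probe sets of Schizosaccharomyces pombe were found, so a background level from the latter and a centring on them, both planned, were not run, and the 25th percentile of the gene means (6.66) took the place of the background level in the alternative without dim genes, which removed 990 genes.

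The values end in a floor near log2 2. Group means under log2 3, a level chosen after the values were seen, are called the floor. In all groups 291 genes (5.34%) lay under it, with a median SD of 0.00529 against 0.103 for the other genes, so a small change at the floor can pass a test. A fold from or to the floor is given as at least the fold between the other group's mean and log2 3, and no fold is given where both groups lay at the floor.

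Each gene was fitted with limma 3.58.1 in R 4.3.3 as 8 group means over all 24 arrays (16 residual degrees of freedom, prior degrees of freedom 1.71), and 16 comparisons were drawn from this fit. They are N-lim against C-lim in the reference strain, each deletion strain against the reference in each medium, snf1Δtor1Δ against each single deletion in each medium, the genetic interaction in each medium, and the interaction of each deletion with the medium. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Comparisons that share a control group share its chance deviations.

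Gene lists (37) were written before the data were examined, as were the tests, the rule for named genes except for its floor, and most of the alternatives. They cover nitrogen catabolite repression targets, amino acid permeases, Gcn4 targets, sulfate and methionine, Cat8 and Adr1 targets, peroxisomal beta-oxidation, hexose transporters and sensors, use of other sugars, glycogen and trehalose, Msn2 and Msn4 targets, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, fatty acid, phospholipid and ergosterol synthesis, respiratory chain and ATP synthase, TCA cycle, retrograde response, mitochondrial ribosome, autophagy, vacuolar hydrolases, glycolysis and ethanol formation, Pho4 targets, proteasome, histones, G1 and S phase genes, a-specific and alpha-specific genes, meiosis, flocculins, selection marker genes, iron uptake, purines and one-carbon, thiamine and pyridoxine, and the factors of Snf1 and of TORC1. Some genes, such as SDH1, SDH2, IDH1 and ATH1, are in more than 1 list. Lists were tested with camera (preset correlation 0.01) with Benjamini-Hochberg adjustment over the 37 lists, and again with a correlation estimated from the data and with fry. Members were counted at the threshold over all genes and, in a second count, with p-values adjusted over the list alone.

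Named genes follow a rule. SNF1 and TOR1 are reported in every group. For the reference comparison and the 6 deletions against the reference, names come from up to 12 genes with the largest rise and 12 with the largest fall past the threshold, with replicate values that do not overlap and a higher mean above the floor, and for the other 9 comparisons from up to 5 each way (no overlap rule for interactions). Of a described list, up to 4 members with the largest change past the threshold may be named, or the one with the smallest p if none passed, and counts of 5 or fewer are named in full. Genes with only a systematic name count but may stay unnamed.

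Whether equal replicate numbers pair cultures was checked once, from the correlation of the arrays' deviations from their group means over genes, before any fits were compared. Every pair of arrays with equal numbers had a correlation over 0.1 for reference C-lim and N-lim (0.23 to 0.37), reference and snf1Δ in N-lim (0.17 to 0.28), reference C-lim and snf1Δ N-lim (0.26 to 0.39), reference C-lim and tor1Δ N-lim (0.23 to 0.40) and snf1Δtor1Δ in both media (0.12 to 0.20). The other groups that share numbers did not meet this, and the labels do not say what the numbers mean.

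Alternatives were another quantile normalization over the tested genes, centring of each array on its median, leaving out dim genes, all probe sets in place of genes, the mean of a gene's probe sets, a trended and robust variance, only the arrays of the comparison, a replicate block as fixed and as random effect (statmod 1.5.0), an added minimum change of 2-fold, and leaving out each array in turn. The comparisons were also repeated on other splits of the same arrays. The scripts were tested on simulated data: 200 changed genes added to simulated values for snf1Δ against the reference in C-lim were recovered at 92.2% for a log2 change of 0.5 and 100% for 1 and 2, with 6.7% of the calls at genes not changed, and for the interaction of snf1Δ with the medium at 68.1%, 98.6% and 100%, with 4.86%. A shift of 0.3 added to the mitochondrial ribosome list was found, with 0 other lists called by camera. The simulated noise was independent between genes, so this run does not test whether the preset correlation suits the real arrays.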

Results

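Transcript levels of the budding yeast Saccharomyces cerevisiae were measured on 24 Affymetrix expression arrays, 1 per chemostat culture. A reference strain and 3 deletion strains, lacking SNF1 (snf1Δ), TOR1 (tor1Δ) or both (snf1Δtor1Δ), were each grown with glucose as the limiting nutrient (C-lim) and with ammonia as the limiting nutrient (N-lim). This gave 8 groups of 3 arrays, which the labels describe as biological replicates. Snf1 is the yeast AMP-activated protein kinase, known for its part in the use of carbon sources other than glucose, and Tor1 is a kinase subunit of TOR complex 1 (TORC1), which ties growth to the nutrient supply. The series asked how the Snf1 and TORC1 pathways act together under the 2 limitations. All cultures grew at a dilution rate of 0.1 per hour, 30 °C and pH 5.0, in a working volume of 0.5 L.

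The deposited log2 values ran from 2.02 to 14.31, with array medians between 7.81 and 7.99, and arrays of 1 group correlated across genes with r between 0.993 and 0.999 (genes are not independent replicates). The first principal component carried 69.2% of the variance. On it the 12 N-lim arrays of all strains lay between 26.84 and 31.59, the 6 C-lim arrays of the reference and tor1Δ between -53.27 and -46.18, and the 6 C-lim arrays of snf1Δ and snf1Δtor1Δ between -11.53 and -5.91. Comparisons used limma on 5449 genes with Benjamini-Hochberg adjustment (adjusted p). Changes are on the log2 scale with their standard error (SE), n = 3 arrays per group throughout, so the number of arrays limits the precision. A gene with a group mean under log2 3 was taken to be at the floor of the arrays, and a change from or to it is given as at least a fold.

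The deleted genes were read first. SNF1 (YDR477W) had a mean of 8.75 ± 0.044 (SD, n = 3) in the reference in C-lim and 8.90 ± 0.15 in N-lim, and 8.84 and 8.95 in tor1Δ. It lay at the floor, at 2.15, in all 4 groups that lack it, at least 53.7-fold lower in C-lim and at least 59.8-fold lower in N-lim. TOR1 (YJR066W) had a mean of 6.94 ± 0.15 in the reference in C-lim and 7.86 ± 0.01 in N-lim, and 7.14 and 7.66 in snf1Δ. It lay at 2.27 in the tor1Δ and snf1Δtor1Δ groups, at least 15.4-fold and at least 29.1-fold lower, so every group carried the deletion its label states. Next to SNF1 in the RefSeq table of assembly R64, YDR476C was lower in snf1Δ by -0.36 in C-lim and -0.44 in N-lim, and SNM1 was higher by 0.45 and 0.33.

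**Figure D1:**
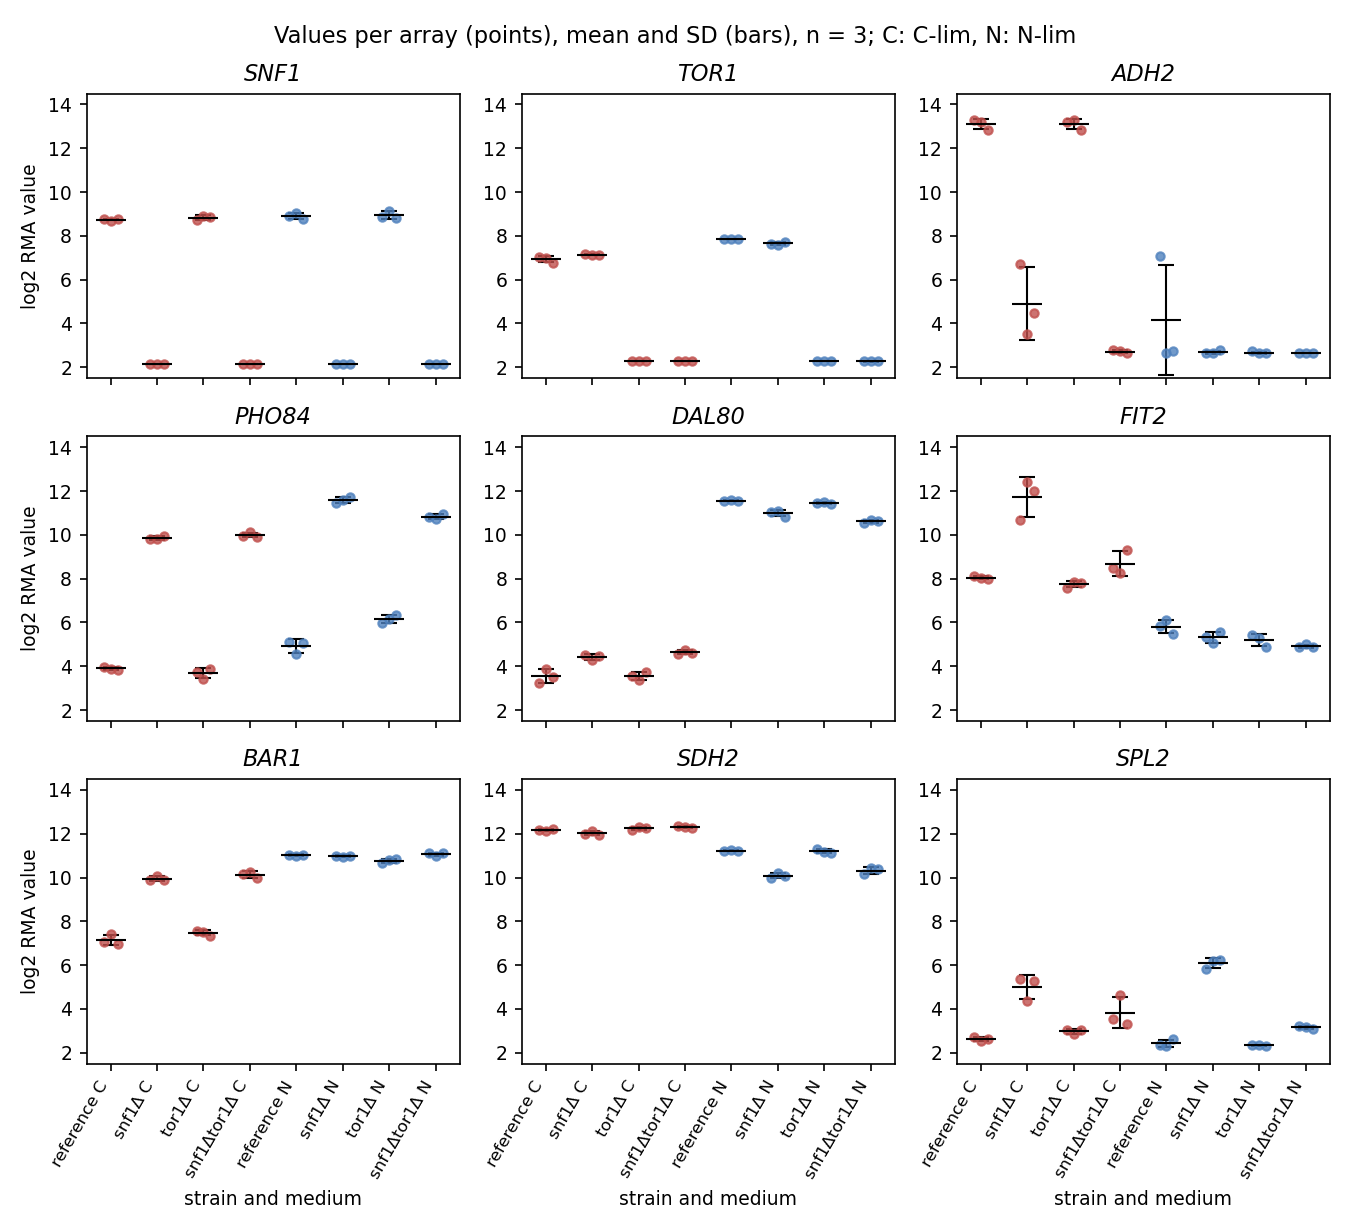
Log2 RMA value (vertical axis) of 9 genes in the 8 groups of strain and medium (horizontal axis), 1 point per array, with the mean and SD of the 3 arrays as bars, C-lim in red and N-lim in blue. SNF1 and TOR1 lie at 2.15 and 2.27 in the strains that lack them, PHO84 rises from 3.90 to 9.86 with the snf1 deletion in C-lim, and 1 of the 3 reference N-lim arrays holds ADH2 at 7.07.

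The reference strain was compared between limitations first. OPT2, an oligopeptide transporter gene, rose in N-lim at least 747-fold. DAL80, encoding a repressor of nitrogen catabolic genes, rose by 8.02 ± 0.12 (SE, adjusted p = 1.5e-19, limma). PTR2, for a peptide transporter, rose by 6.65 ± 0.18, and the allantoate permease gene DAL5 by 6.08 ± 0.12. The alpha-factor gene MF(ALPHA)1 rose by 7.37 ± 0.16, from 4.63 to 11.99, HXT1, for a low-affinity glucose transporter, at least 58.4-fold, and the pyruvate decarboxylase gene PDC5 by 5.998 ± 0.16. SFC1, for a mitochondrial succinate-fumarate carrier, fell at least 308-fold, the acetate transporter gene ADY2 at least 251-fold, FDH1, for formate dehydrogenase, at least 430-fold, and RGI2, known from respiratory growth, at least 571-fold. ADH2, for the glucose-repressed alcohol dehydrogenase, fell by 8.95 ± 0.84 from 13.11, with 1 N-lim array at 7.07 and the other 2 at 2.64 and 2.76. In all, 3661 of 5449 genes changed at an adjusted p under 0.05, 2259 higher and 1402 lower in N-lim, of which 376 and 381 changed at least 2-fold. Median-centred, with floor genes lowered too, the split was 1845 and 2024, but 2094 and 1558 after another quantile normalization.

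Gene lists fixed before the data were examined gave the direction of whole groups in N-lim against C-lim. Of 25 targets of nitrogen catabolite repression, 21 rose and 3 fell (GDH2, MEP1 and UGA1), and these counts were equal when adjusted over the list alone (camera adjusted p = 4.88e-07; adjusted p = 0.2 with an estimated correlation). Of 19 Cat8 and Adr1 targets, genes of gluconeogenesis, the glyoxylate cycle and the use of C2 compounds, 18 fell and MLS1 rose, with FBP1 at least 54.1-fold lower. This call held both ways (camera adjusted p = 1.52e-13; adjusted p = 0.0287 with an estimated correlation). All 7 a-specific genes, which are expressed in cells of mating type a, rose, among them BAR1 by 3.86 ± 0.10 and MFA1 by 2.83 ± 0.08 (camera adjusted p = 9.14e-06; adjusted p = 0.0287 with an estimated correlation). All 25 stress genes driven by Msn2 and Msn4 fell, with GRE1 lower by -8.39 ± 0.49 and SIP18 by -6.89 ± 0.42 (camera adjusted p = 8.18e-14; adjusted p = 0.2 with an estimated correlation). For the 4 lists the counts adjusted over the list alone were the same.

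Among lists of lipid and mitochondrial genes, all 14 genes of phospholipid synthesis rose in N-lim, CKI1 by 2.41 ± 0.08 and PSD1 by 2.08 ± 0.12 (camera adjusted p = 1.67e-06; adjusted p = 0.0822 with an estimated correlation). Of 18 genes of peroxisomal beta-oxidation 15 fell and OAF1 and PIP2 rose, with CTA1, for a catalase, at least 147-fold lower (adjusted p = 0.2 with an estimated correlation). Of 66 genes of the mitochondrial ribosome 51 fell, MRP20 by -0.92 ± 0.05, and MRPL33 rose (adjusted p = 0.245 with an estimated correlation). Of 37 genes of the respiratory chain and ATP synthase 22 fell, NDE2 by -5.27 ± 0.18, and COX9 rose (adjusted p = 0.2 with an estimated correlation). TCA cycle genes went the same way, 12 of 15 lower and IDH1 and IDH2 higher (adjusted p = 0.2 with an estimated correlation). So did 13 of 24 ergosterol genes, HMG1 by -1.45 ± 0.05, with ERG10, ERG20, MVD1 and NCP1 higher (adjusted p = 0.245 with an estimated correlation). The camera adjusted p of these lists ran from 9.09e-11 to 0.00118, and all counts were equal adjusted over the list alone. With median-centred arrays 16 ergosterol genes were lower and fewer higher.

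Camera called 11 other lists in N-lim against C-lim. Higher were 9 of 14 Pho4 targets, with PHO89 lower, all 9 histone genes and 15 of 19 G1 and S phase genes, with PRI1 lower (16 and 1 adjusted over the list alone). Of 24 genes of TORC1 and its factors 19 were higher, such as MSN4 by 2.54 ± 0.10 and GAT1 by 1.69 ± 0.10. Lower were 25 of 44 amino acid biosynthesis genes driven by Gcn4, with 12 higher, and 7 of 12 genes for the use of sucrose, galactose and maltose, with GAL80 and MAL13 higher. So were 11 of 16 glycogen and trehalose genes, with GPH1, NTH1, TPS3 and UGP1 higher, and 25 of 71 ribosome biogenesis genes, with BFR2, DIP2, NOC3, UTP10 and UTP22 higher (24 and 3 adjusted over the list alone). Autophagy had 16 lower and 7 higher of 34 genes. The meiosis list had 7 lower genes of 15 and SPO11 and SPS4 higher, and the thiamine and pyridoxine list 6 lower of 10 and THI20, THI21, THI22 and THI7 higher. The camera adjusted p lay between 0.000475 and 0.0417 for the 11 lists, and with an estimated correlation all 11 were lost, at adjusted p = 0.2 to adjusted p = 0.729. The meiosis list was also lost after another quantile normalization (adjusted p = 0.102), and the thiamine list with median-centred arrays (adjusted p = 0.0776). With median-centred arrays 39 and after another quantile normalization 32 ribosome biogenesis genes were lower and fewer higher. Median-centred, 12 meiosis genes were lower, but 5 of 15 always lay at the floor.

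In C-lim, the deletion of SNF1 raised PHO84, for the high-affinity phosphate transporter, by 5.96 ± 0.13, from 3.90 to 9.86 (adjusted p = 7.3e-17, limma), and the acid phosphatase gene PHO5 rose at least 11.9-fold from the floor. EEB1, for an ethyl ester synthase, rose by 4.35 ± 0.09, PTR2 by 4.12 ± 0.18, the carnitine carrier gene CRC1 by 3.50 ± 0.18, and the iron genes FIT2 and FET3 by 3.67 ± 0.32 and 3.46 ± 0.31. ADH2 fell by 8.202 ± 0.84, from 13.11 to 4.90 ± 1.7 (SD). Falls were also found for FDH1 by -7.64 ± 0.57, GRE1 by -7.63 ± 0.49, ADY2 by -7.18 ± 0.40, SPS100, a spore wall gene, by -6.57 ± 0.26, and AQY1, for an aquaporin, by -6.55 ± 0.39. In total 3383 genes changed, 2207 higher and 1176 lower, of which 182 and 330 changed at least 2-fold.

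Several lists moved as a whole with the SNF1 deletion in C-lim. All 25 stress genes fell, SIP18 by -5.43 ± 0.42 and GND2 by -4.35 ± 0.22 (camera adjusted p = 4.12e-19; adjusted p = 0.146 with an estimated correlation). Of 19 Cat8 and Adr1 targets 15 fell while CRC1 and YAT1 rose, with FBP1 lower by -4.46 ± 0.15 (camera adjusted p = 8.5e-07; adjusted p = 0.146 with an estimated correlation). All 7 a-specific genes rose, BAR1 by 2.80 ± 0.10 (camera adjusted p = 2.74e-05; adjusted p = 0.0628 with an estimated correlation). So did all 7 targets of the retrograde response, the signalling from mitochondria to nucleus, CIT2 by 2.01 ± 0.10 (camera adjusted p = 0.000301; adjusted p = 0.168 with an estimated correlation). Of 14 Pho4 targets 13 rose and PHM8 fell (camera adjusted p = 0.000301; adjusted p = 0.146 with an estimated correlation). Of 18 iron uptake genes 15 rose and FRE4 fell, at least 5.15-fold (camera adjusted p = 0.00448; adjusted p = 0.478 with an estimated correlation). None of the 20 lists called by camera in this comparison held with an estimated correlation, while fry, which tests a list by itself, called 33 of 37.

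The other calls of this comparison were of 14 lists. Higher were 11 of 13 amino acid permeases, with BAP2 lower, DIP5 at least 4.57-fold and GNP1 by 2.06 ± 0.14. Gcn4 targets were higher in 37 of 44, with LEU4 lower (39 and 1 adjusted over the list alone), as were 18 of 23 sulfate and methionine genes, with STR3 lower (19 and 2 adjusted over the list alone). Of 14 phospholipid genes 12 rose, INO1 by 1.51 ± 0.07. Also higher were 60 of 66 mitochondrial ribosome genes, with MRP8 lower (60 and 2 adjusted over the list alone), and 25 of 37 respiratory chain genes, with NDE2 lower. Lower were 12 of 18 beta-oxidation genes, with ANT1, MDH3 and PIP2 higher, and 12 of 16 glycogen and trehalose genes, with TPS3 higher (13 and 1 adjusted over the list alone). Of 24 ergosterol genes 15 fell, with ERG10, ERG20, ERG4, ERG8 and MVD1 higher, and of 34 autophagy genes 22, with ATG10 and ATG41 higher (23 and 2 adjusted over the list alone). Of 10 vacuolar hydrolases 9 fell, AMS1 by -1.80 ± 0.13, with PHO8 higher. Lower too were 12 of 33 proteasome genes, with RPN1 higher (12 and 0 adjusted over the list alone), 6 of 9 histone genes and 8 of 15 meiosis genes, with SPO11 and SPS4 higher. Their camera adjusted p ran from 1.72e-07 to 0.0437, and with an estimated correlation all were lost, from adjusted p = 0.146 to adjusted p = 0.487. The respiratory chain call also ended with median-centred arrays, where 15 members rose and 1 fell (adjusted p = 0.0859), and the meiosis call after another quantile normalization (adjusted p = 0.0642). Fewer ergosterol genes were higher with median-centred arrays.

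In N-lim the SNF1 deletion again raised PHO84, by 6.67 ± 0.13 from 4.92 to 11.59 (adjusted p = 5e-17, limma), PHO5 at least 10.5-fold and SPL2, a regulator of low-affinity phosphate uptake, at least 8.52-fold. STL1, for a glycerol symporter, rose at least 10.6-fold, YET2 by 3.12 ± 0.19 and PRM10, named for its pheromone regulation, by 2.84 ± 0.14. PRM6 fell by 2.82 ± 0.12 and MF(ALPHA)1 fell by 2.35 ± 0.16. HXT7, for a high-affinity hexose transporter, changed by -2.17 ± 0.16, the maltase gene MAL32 by -2.02 ± 0.24 and the glycogen phosphorylase gene GPH1 by -1.89 ± 0.14. In total 1694 genes changed, 766 higher and 928 lower, of which 74 and 55 changed at least 2-fold. The split depended on the scaling, 843 and 830 median-centred and 851 and 934 quantile-normalized again.

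Of the lists, 3 held in both forms of the test in snf1Δ against the reference in N-lim. Of 37 genes of the respiratory chain and ATP synthase, 34 fell and 0 rose (35 and 0 adjusted over the list alone). SDH2, for a succinate dehydrogenase subunit, changed by -1.14 ± 0.07 and COX4 by -0.68 ± 0.08 (camera adjusted p = 7e-22; adjusted p = 0.0071 with an estimated correlation). All 15 TCA cycle genes fell, KGD2 by -0.71 ± 0.06 (camera adjusted p = 1.68e-13; adjusted p = 0.0151 with an estimated correlation). Of 14 Pho4 targets 12 rose, VTC3 by 1.16 ± 0.06 (camera adjusted p = 3.32e-09; adjusted p = 0.0124 with an estimated correlation). For the TCA cycle and Pho4 lists the counts adjusted over the list alone were the same.

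Another 13 lists were called by camera in this comparison, at adjusted p from 3.71e-09 to 0.0459, and lost with an estimated correlation, at adjusted p = 0.285 to adjusted p = 0.794. Higher were 34 of 71 ribosome biogenesis genes (40 adjusted over the list alone), DRS1 by 0.65 ± 0.13, and 10 of 20 genes of RNA polymerases I and III. Cytosolic ribosomal protein genes had 7 of 128 higher (0 adjusted over the list alone, limma; 34 at an unadjusted p under 0.05), but 23 after another quantile normalization and 11 with median-centred arrays. Gcn4 targets had 13 of 44 higher, with ARG1, ARG4 and SER3 lower (14 and 3 adjusted over the list alone). Lower were 8 of 16 glycogen and trehalose genes and 4 of 12 genes for the use of other sugars (MAL32, MAL11, MAL31 and MAL13; 6 adjusted over the list alone). Autophagy had 16 of 34 genes lower, with ATG17, ATG27, ATG41 and ATG5 higher (17 and 4 adjusted over the list alone). The mitochondrial ribosome had 12 of 66 lower, with RSM19 higher (9 and 1 adjusted over the list alone). Lower too were 3 histone genes (HHO1, HTA1 and HTZ1) of 9 (4 adjusted over the list alone) and 4 a-specific genes (AGA2, ASG7, MFA2 and STE2) of 7. Snf1 and its factors had 8 of 18 lower, with SIP1 and TOS3 higher. SNF1 is among the 8, and no test left it out. TORC1 and its factors had 10 of 24 lower, MSN4 by -1.10 ± 0.10. The 3 lower alpha-specific genes were MF(ALPHA)1, SAG1 by -0.61 ± 0.10 and MF(ALPHA)2, which lay at the floor in both groups and did not pass with the replicate block (3 lower and 1 higher adjusted over the list alone). The histone and alpha-specific calls ended with median-centred arrays (adjusted p = 0.0919 and adjusted p = 0.0522).

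**Figure D2:**
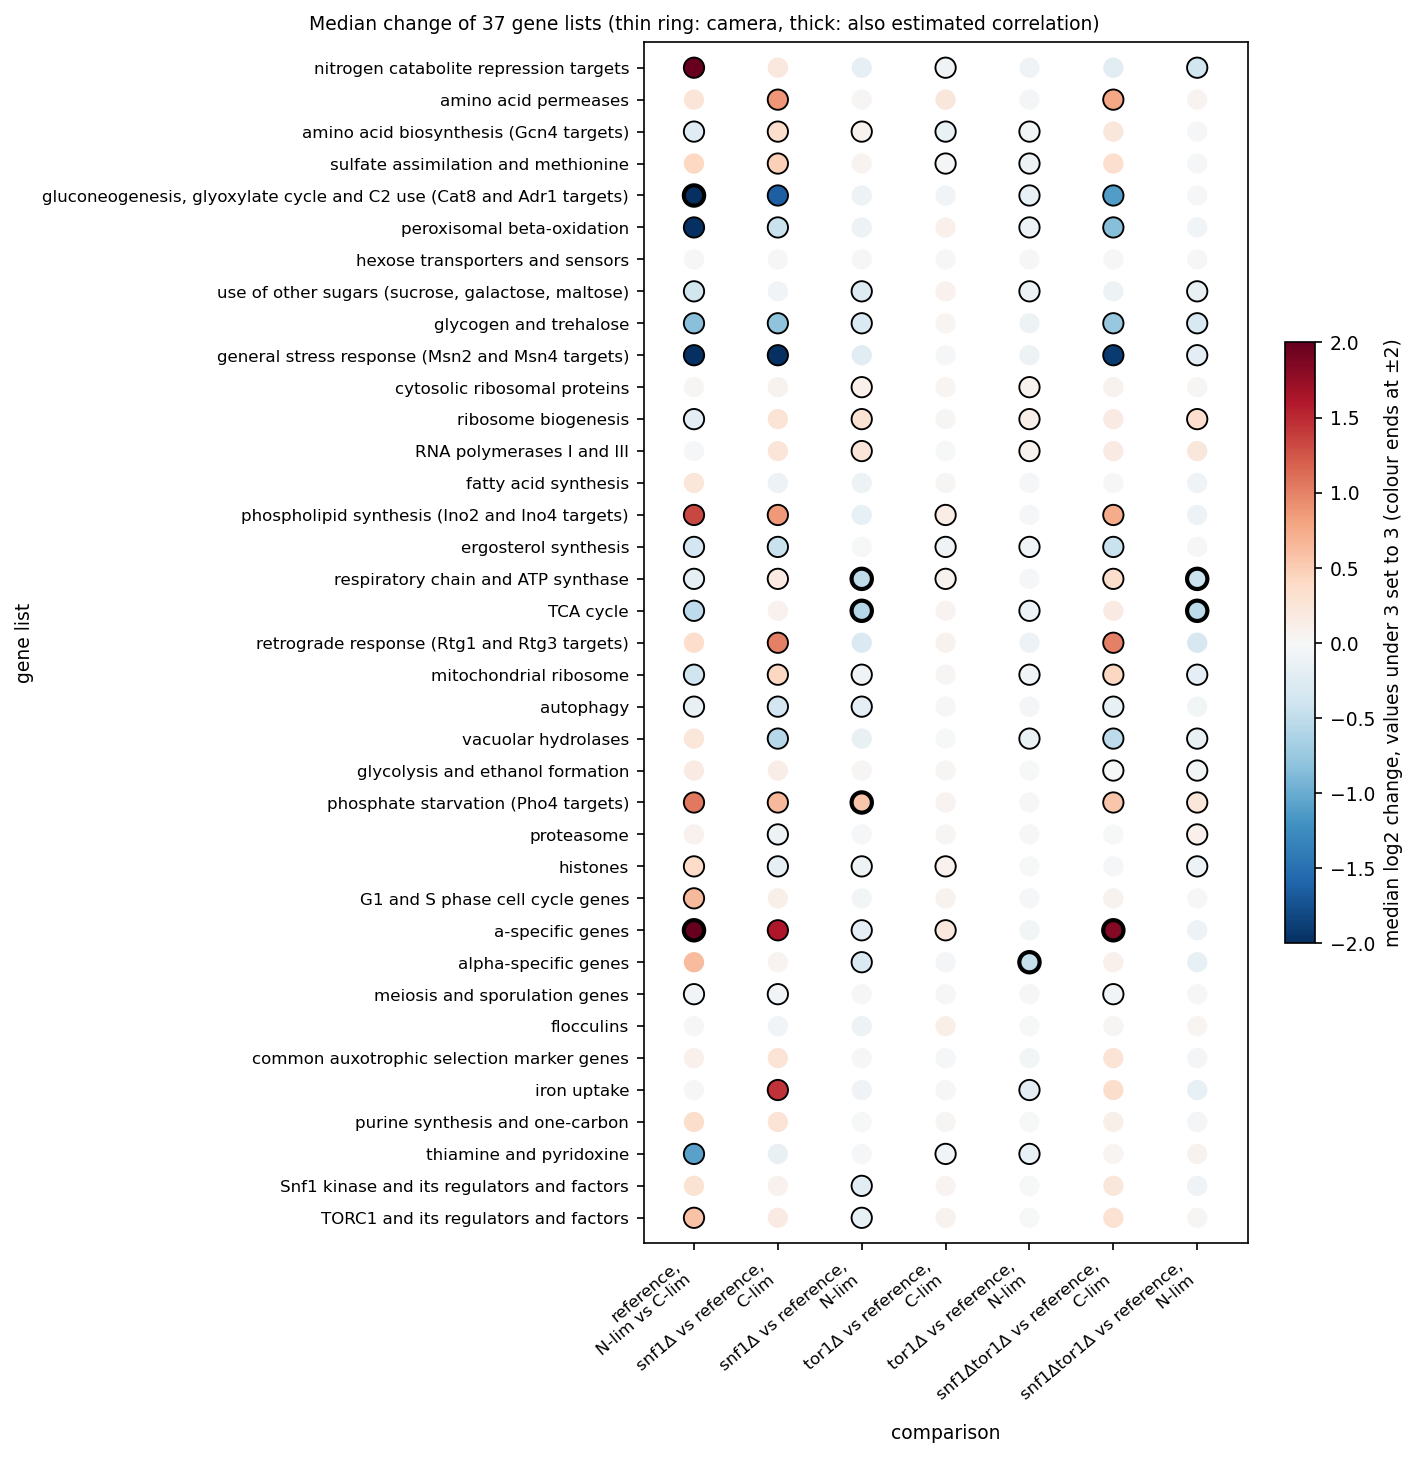
Median log2 change (colour, limited to ±2, with values under 3 set to 3) of the 37 gene lists (vertical axis) in 7 comparisons (horizontal axis), with a thin ring where camera called the list and a thick ring where it was also called with an estimated correlation. The respiratory chain list is lower in snf1Δ in N-lim with a median of -0.501 and called both ways, while in C-lim its median is 0.187, and the stress list is at -2.15 in snf1Δ in C-lim.

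The effect of the SNF1 deletion was then compared between limitations as an interaction, N-lim effect minus C-lim effect. It was positive for all 25 stress genes, GRE1 by 8.66 ± 0.69 (camera adjusted p = 3.84e-20; adjusted p = 0.09 with an estimated correlation) and SPS100 by 7.66 ± 0.37. It was negative for all 7 a-specific genes, BAR1 by -2.83 ± 0.14 (camera adjusted p = 5.34e-07; adjusted p = 0.0149 with an estimated correlation). It was also negative for 36 of 37 respiratory chain genes, SDH2 by -1.004 ± 0.10, with NDE2 positive by 1.06 ± 0.26 (camera adjusted p = 3.18e-12; adjusted p = 0.0498 with an estimated correlation). Negative too were all 7 retrograde targets, CIT2 by -1.63 ± 0.14 (camera adjusted p = 1.48e-05; adjusted p = 0.09 with an estimated correlation), and 13 of 15 TCA cycle genes, with LSC1 positive, IDH2 by -1.70 ± 0.11 (camera adjusted p = 8.16e-06; adjusted p = 0.145 with an estimated correlation). So were 60 of 66 mitochondrial ribosome genes, with MRP8 positive (61 and 1 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). Pho4 targets, with PHM8, PHO84 and SPL2 positive and PHM6, PHO8 and PHO81 negative of 14, were not called (camera adjusted p = 0.949).

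In total 2571 genes differed in their response to the SNF1 deletion between limitations (limma), 881 positive and 1690 negative, of which 295 and 210 differed at least 2-fold. YDL218W, ADY2 and FDH1, with interactions of 8.59, 6.99 and 6.91, lay at the floor in both N-lim groups, so their values are limited by the floor. Negative interactions were found for SIT1, a siderophore transporter gene, at -4.70 ± 0.51, PTR2 at -4.91 ± 0.26 and EEB1 at -4.67 ± 0.13. Of 18 iron uptake genes 14 were negative and FRE4 positive (adjusted p = 0.481 with an estimated correlation), and of 19 Cat8 and Adr1 targets 13 were positive and CRC1 and YAT1 negative (adjusted p = 0.154 with an estimated correlation). Of 14 phospholipid genes 12 were negative, and of 24 ergosterol genes 14 were positive and ERG20 and MVD1 negative (15 and 2 adjusted over the list alone; adjusted p = 0.09 with an estimated correlation for both lists). Camera called 20 lists, 9 of them positive and 11 negative. With an estimated correlation 2 held, the a-specific genes and the respiratory chain, and the others were lost, at adjusted p = 0.09 to adjusted p = 0.671.

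The TOR1 deletion in C-lim changed few genes. SPS4, a sporulation gene, rose by 1.06 ± 0.17 (adjusted p = 0.0038, limma), the cell wall glucanase genes SCW11 and DSE4 by 0.60 ± 0.13 and 0.43 ± 0.09, and HO, for the mating-type endonuclease, by 0.46 ± 0.09. BIO5, for a transporter of a biotin precursor, fell by 1.19 ± 0.15 (adjusted p = 0.00029), and HES1, for an oxysterol-binding protein homologue, by -0.71 ± 0.08. The peroxiredoxin gene TSA2 changed by -0.73 ± 0.13 and the cell wall genes PAU18 and TIR1 by -0.87 ± 0.20 and -0.82 ± 0.16. In total 58 genes changed, 33 higher and 25 lower, of which 1 and 2 changed at least 2-fold, SPS4, BIO5 and TOR1 itself, and with median-centred arrays the split was 17 and 34. The count depended on single arrays. It was 184 without reference C-lim replicate 10, 24 without reference replicate 11, and 32, 34 and 21 without tor1Δ replicates 07, 08 and 09. It was 2 in a fit of only the 6 arrays of the comparison.

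Camera called 9 lists for tor1Δ in C-lim, mostly from small shifts of many members. The Gcn4 targets were lower with a median of -0.13 over 44 genes, 1 of which, ARG1, fell by 0.30 ± 0.05 (10 fell adjusted over the list alone; camera adjusted p = 2.38e-15; adjusted p = 0.198 with an estimated correlation). In the ergosterol list ERG24 alone of 24 fell (5 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). In the nitrogen catabolite repression list GLN1 alone of 25 fell (4 adjusted over the list alone; adjusted p = 0.441 with an estimated correlation), and in the sulfate list STR3 alone of 23 (adjusted p = 0.954 with an estimated correlation). In the phospholipid list INO1 alone of 14 rose (adjusted p = 0.441 with an estimated correlation). In 4 lists camera found a shift although 0 members passed limma over all genes. It was higher for the respiratory chain (5 of 37 at an unadjusted p under 0.05), histones (4 of 9) and a-specific genes (4 of 7), and lower for thiamine and pyridoxine (3 of 10). Adjusted over the list alone, 0, 3, 3 and 3 members passed, and with an estimated correlation the lists gave adjusted p = 0.755, adjusted p = 0.441, adjusted p = 0.331 and adjusted p = 0.331. The sulfate call ended after another quantile normalization (adjusted p = 0.173). Those of the respiratory chain, histones and thiamine ended with median-centred arrays (adjusted p = 0.108, adjusted p = 0.145 and adjusted p = 0.0728). Only 5 lists were called without reference C-lim replicate 09.

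In N-lim the TOR1 deletion lowered more genes than it raised. SUL1, for a high-affinity sulfate permease, fell by 2.42 ± 0.19, from 9.44 to 7.02 (adjusted p = 9e-07, limma). The dicarboxylic amino acid permease gene DIP5 changed by -1.65 ± 0.34, the decarboxylase genes ARO10 and PDC6 by -1.60 ± 0.23 and -1.37 ± 0.15. CDA1, for a chitin deacetylase, fell at least 2.94-fold. PHO84 rose by 1.24 ± 0.13 (adjusted p = 2.5e-05), the allantoin genes DAL4, DAL3 and DAL2 by 0.93 ± 0.17, 0.71 ± 0.14 and 0.52 ± 0.12, and the aquaporin gene AQY2 by 0.86 ± 0.11. In total 159 genes changed, 39 higher and 120 lower, of which 1, PHO84, and 12 changed at least 2-fold, and after another quantile normalization the split was 59 and 97. The count was 86, 88 and 93 without reference N-lim replicates 09, 10 and 11, 104 without tor1Δ replicate 09, and 67 in a fit of only the 6 arrays of the comparison.

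Of the 15 lists camera called for tor1Δ in N-lim, the alpha-specific genes held both ways. STE3, for the a-factor receptor, fell by 0.69 ± 0.15 and MF(ALPHA)1 by -0.62 ± 0.16, with SAG1 and MF(ALPHA)2, the latter at the floor in both groups, also lower adjusted over the list alone (camera adjusted p = 8.21e-05; adjusted p = 0.0264 with an estimated correlation). Lower were 7 of 44 Gcn4 targets, SER3 by -0.67 ± 0.11, and 4 sulfate genes of 23 (SUL1, CYS4, MET2 and MET28). So were 3 thiamine and pyridoxine genes of 10 (THI4, SNZ3 and SNO3) and 2 genes for other sugars of 12 (MAL32 and MAL11). Lower too were 2 ergosterol genes of 24 (ERG24 and ERG10), and 1 gene each of beta-oxidation (POT1 of 18), vacuolar hydrolases (APE4 of 10) and iron uptake (FET3 of 18). Adjusted over the list alone these counts were 7 lower and 3 higher, 7, 4, 3, 2, 7, 1 and 1. With no member past limma over all genes, camera placed cytosolic ribosomal proteins, ribosome biogenesis and RNA polymerases I and III higher (9 of 128, 9 of 71 and 3 of 20 members at an unadjusted p under 0.05). It placed Cat8 and Adr1 targets, the TCA cycle and the mitochondrial ribosome lower (3 of 19, 6 of 15 and 13 of 66). Adjusted over the list alone, 4 TCA cycle genes fell and 0 members of the other 5 lists passed limma. With an estimated correlation the other 14 lists were lost, at adjusted p = 0.158 to adjusted p = 0.801. The RNA polymerase call ended after another quantile normalization (adjusted p = 0.0574) and the ergosterol call with median-centred arrays (adjusted p = 0.0688). The nitrogen catabolite repression targets, with DAL2, DAL3 and DAL4 higher and OPT2 lower of 25, were not called (camera adjusted p = 0.716).

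Between limitations, the effect of the TOR1 deletion differed for 53 genes (limma), 15 positive and 38 negative in N-lim minus C-lim, of which 4 (DAL4, PHO84, BIO5 and OYE3) and 9 differed at least 2-fold. The interaction was positive for DAL4 at 1.58 ± 0.24, DAL3 at 0.88 ± 0.20 and PHO84 at 1.47 ± 0.19, and negative for SUL1 at -2.23 ± 0.28 and ARO10 at -1.37 ± 0.32. CDA1, at the floor in tor1Δ in N-lim, was negative as well. BIO5, at 1.19 ± 0.21, lay at the floor in both N-lim groups, so its value is that of C-lim. DAL4 and DAL3 were the members past the threshold in the nitrogen catabolite repression list of 25 (4 positive and 2 negative adjusted over the list alone), and LYS21 that of the 44 Gcn4 targets (3 and 3 adjusted over the list alone). Camera called 15 lists, all lost with an estimated correlation, at adjusted p = 0.24 to adjusted p = 0.791. The calls of other sugars, RNA polymerases, ergosterol and G1 and S phase genes ended after another quantile normalization (adjusted p = 0.0578 to adjusted p = 0.0868). Those of RNA polymerases and the respiratory chain ended with median-centred arrays (adjusted p = 0.0583 and adjusted p = 0.15). With median-centred arrays the gene split was 25 and 23. The count was 86 without reference C-lim replicate 10, and 30 without replicate 11. It was 30, 35 and 34 without reference N-lim replicates 09, 10 and 11. It was 24 without tor1Δ C-lim replicate 09, 28 without tor1Δ N-lim replicate 11, and 31 in a fit of only the 12 arrays of the comparison. With the replicate block, 10 genes passed, 3 positive and 7 negative, and DAL4, DAL3, PHO84, OYE3, ARO10 and LYS21 did not.

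Loss of both kinases in C-lim was compared with the reference. The snf1Δtor1Δ cultures share no replicate number with the other strains. If the numbers mark series of cultures, such a series cannot be told apart from the deletions when this strain is compared within a medium. ADH2 fell from 13.11 to the floor, at least 1100-fold, RGI2 at least 571-fold, FDH1 at least 430-fold, ADY2 at least 251-fold and AQY1 at least 124-fold, and GRE1 fell by 7.46 ± 0.49 (adjusted p = 3.3e-10, limma). PHO84 rose by 6.09 ± 0.13, EEB1 by 4.50 ± 0.09, PTR2 by 4.09 ± 0.18, CRC1 by 3.27 ± 0.18, SST2, a regulator of pheromone desensitization, by 3.02 ± 0.13 and PHO5 at least 8.85-fold. In total 3348 genes changed, 2326 higher and 1022 lower, of which 188 and 298 changed at least 2-fold. The median over all genes was shifted by 0.131, and relative to it, with median-centred arrays, 1887 were higher and 1508 lower.

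Of the lists in this comparison, all 7 a-specific genes rose, BAR1 by 2.99 ± 0.10 and ASG7 by 2.31 ± 0.14, and the call held both ways (camera adjusted p = 1.75e-05; adjusted p = 0.0481 with an estimated correlation). All 25 stress genes fell (camera adjusted p = 1.85e-20; adjusted p = 0.168 with an estimated correlation). All 7 retrograde targets rose, CIT2 by 2.19 ± 0.10, as did 12 of 14 Pho4 targets and 12 of 14 phospholipid genes (adjusted p = 0.168 with an estimated correlation for each). Other calls were 11 of 13 amino acid permeases higher with BAP2 lower by -3.56 ± 0.25, and 30 of 37 respiratory chain genes higher with NDE2 lower (32 and 1 adjusted over the list alone). Of 66 mitochondrial ribosome genes 58 rose with MRP20 and MRP8 lower. Lower were 13 of 19 Cat8 and Adr1 targets with CRC1, ICL1, PCK1 and YAT1 higher and 13 of 18 beta-oxidation genes with ANT1, MDH3, OAF1 and PIP2 higher. Also lower were 12 of 16 glycogen and trehalose genes with TPS3 higher and 15 of 24 ergosterol genes with ERG10, ERG12, ERG4, ERG8 and MVD1 higher. The other lower lists were autophagy, 16 of 34 with ATG10, ATG12, ATG26 and ATG5 higher, vacuolar hydrolases, 9 of 10 with PHO8 higher, and meiosis, 8 of 15 with SPO11 and SPS4 higher. With an estimated correlation these were lost, at adjusted p = 0.168 to adjusted p = 0.486. Glycolysis and ethanol formation, with 7 lower and 6 higher of 20, PDC6 lower by -2.72 ± 0.15, was called lower (camera adjusted p = 0.0499; adjusted p = 0.671 with an estimated correlation). But after another quantile normalization 7 were higher and 5 lower and the call ended (adjusted p = 0.281). The meiosis call ended there too (adjusted p = 0.0695). Again fewer ergosterol genes were higher with median-centred arrays.

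In N-lim the snf1Δtor1Δ strain was compared with the reference as well. PHO84 rose by 5.92 ± 0.13 (adjusted p = 2.7e-16, limma), PHO5 at least 7.47-fold, STL1 at least 5.03-fold, PRM10 by 2.95 ± 0.14 and HXT5, for a hexose transporter, by 2.29 ± 0.37. RSB1, for a sphingoid base transporter, fell at least 14.2-fold, MAL32 at least 8.16-fold, HXT7 by -2.92 ± 0.16, SUL1 by -2.52 ± 0.19, MLS1, for malate synthase, by -2.47 ± 0.15 and GPH1 by -2.42 ± 0.14. In total 2194 genes changed, 1303 higher and 891 lower, of which 80 and 65 changed at least 2-fold. The majority of higher genes rests on the scaling, since the split was 1051 and 1065 with median-centred arrays and 1097 and 1076 after another quantile normalization.

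The respiratory chain and TCA cycle lists held in both forms of the test in this comparison. Of 37 respiratory chain genes 32 fell and 0 rose, SDH2 by -0.91 ± 0.07 (camera adjusted p = 7.29e-18; adjusted p = 0.0186 with an estimated correlation). All 15 TCA cycle genes fell, KGD2 by -0.78 ± 0.06 and CIT1 by -0.69 ± 0.06 (camera adjusted p = 2.16e-13; adjusted p = 0.0234 with an estimated correlation). Camera also called 11 lists that were lost with an estimated correlation, at adjusted p = 0.419 to adjusted p = 0.666. Lower were 14 of 25 nitrogen catabolite repression targets, with DAL3, GDH2, MEP1, MEP3 and UGA4 higher (15 and 5 adjusted over the list alone). Among them were OPT2 by -2.001 ± 0.12 and DUR3, for a urea permease, by -1.44 ± 0.16. The mitochondrial ribosome had 36 of 66 genes lower, with MRPL32 higher (37 and 2 adjusted over the list alone). Stress genes had 10 of 25 lower, with ALD3, CTT1 and FMP45 higher, and glycogen and trehalose 9 of 16 (10 adjusted over the list alone). Lower too were 5 of 12 genes for other sugars (MAL11, MAL31, MAL32, MAL33 and SUC2), with GAL3 higher, and 5 of 20 genes of glycolysis and ethanol formation (ENO1, HXK1 by -1.90 ± 0.08, PDC5, PDC6 and TDH1). The last were 4 of 10 vacuolar hydrolases (APE1, APE4, CPS1 and PRB1), with AMS1 higher, and 4 histone genes (HHO1, HTZ1, HTB1 and HTA1) of 9. Higher were 39 of 71 ribosome biogenesis genes (42 adjusted over the list alone), 7 of 14 Pho4 targets (9 adjusted over the list alone) and 10 of 33 proteasome genes (9 adjusted over the list alone). The glycolysis and histone calls ended after another quantile normalization (adjusted p = 0.144 for both), with fewer histone genes lower, and the proteasome call with median-centred arrays, with fewer genes higher (adjusted p = 0.133). After another quantile normalization 22 proteasome genes were higher (adjusted p = 1.6e-05).

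Between limitations, the effect of losing both kinases differed for 2543 genes (limma), 975 positive and 1568 negative, of which 302 and 228 differed at least 2-fold. RGI2, FDH1, YDL218W and ADY2, with interactions from 8.36 to 9.34, lay at the floor in both N-lim groups, and all 4 also in snf1Δtor1Δ in C-lim, so these values are limited by the floor. ADH2 was positive too, but lay at the floor in snf1Δtor1Δ in both media and had 1 reference N-lim array at 7.07, so no size is given. All 7 a-specific genes were negative, BAR1 by -2.94 ± 0.14 (camera adjusted p = 2.14e-07; adjusted p = 0.0113 with an estimated correlation). So were 36 of 37 respiratory chain genes, COX6 by -1.08 ± 0.11, with NDE2 positive (camera adjusted p = 3.37e-14; adjusted p = 0.0274 with an estimated correlation). The stress list was positive for all 25 genes (camera adjusted p = 5.98e-16; adjusted p = 0.136 with an estimated correlation). Of 66 mitochondrial ribosome genes 60 were negative with MRP8 positive (61 and 1 adjusted over the list alone; adjusted p = 0.283 with an estimated correlation). Camera called 18 lists, 9 positive and 9 negative. With an estimated correlation 2 held, the a-specific genes and the respiratory chain, and the others were lost, at adjusted p = 0.123 to adjusted p = 0.787. Among those lost, the meiosis call also ended after another quantile normalization (adjusted p = 0.0527). PTR2 and EEB1 had interactions of -5.03 ± 0.26 and -4.95 ± 0.13.

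To see what the TOR1 deletion adds in cells without SNF1, snf1Δtor1Δ was set against snf1Δ. A separate series of snf1Δtor1Δ cultures cannot be told apart from this effect in either medium. In C-lim the gluconeogenic genes PCK1 and FBP1 rose by 2.55 ± 0.13, from 6.64 to 9.19 (adjusted p = 5.6e-10, limma), and 2.05 ± 0.15, HXT4 by 1.94 ± 0.24 and PHM8, for a phosphatase, by 1.69 ± 0.17. STL1 fell at least 11.8-fold, and the iron genes FIT3 and FIT2, for cell wall mannoproteins, fell by 3.50 ± 0.32 and -3.03 ± 0.32. Of 18 iron uptake genes 13 fell and 0 rose (14 adjusted over the list alone), SIT1 by -2.05 ± 0.36 and FET3 by -1.68 ± 0.31 (camera adjusted p = 5.15e-12; adjusted p = 0.261 with an estimated correlation). In snf1Δ in C-lim these genes varied between arrays, FIT2 with a mean of 11.71 ± 0.91 (SD) against 8.68 ± 0.56 in snf1Δtor1Δ. In total 937 genes changed, 586 higher and 351 lower, of which 22 and 34 changed at least 2-fold, and with median-centred arrays the split was 413 and 466. The count was 517 and 521 without snf1Δtor1Δ replicates 01 and 02, 612 without snf1Δ replicate 10, and 401 in a fit of only the 6 arrays of the comparison.

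The TOR1 deletion in snf1Δ in C-lim also went with lower Gcn4 targets, 14 of 44 (18 adjusted over the list alone), LEU9 by -0.68 ± 0.13. Lower too were sulfate and methionine genes, 11 of 23 (13 adjusted over the list alone), SUL1 by -1.60 ± 0.19, and glycolysis genes, 9 of 20 (10 adjusted over the list alone), TDH1 by -0.39 ± 0.06. Each had 0 higher genes by limma (camera adjusted p from 5.06e-11 to 1e-09; adjusted p = 0.261 with an estimated correlation for each). Nitrogen catabolite repression targets had 10 lower of 25 and DAL5 higher, GAP1, for the general amino acid permease, by -0.79 ± 0.17 (13 and 1 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). Higher were 10 of 34 autophagy genes, with ATG41 lower (19 and 1 adjusted over the list alone), 8 of 37 respiratory chain genes, 7 of 33 proteasome genes, with RPT3 lower, and 2 of 7 a-specific genes, ASG7 and MFA1. Lower were 4 of 13 amino acid permeases (AGP1, BAP2, BAP3 and GNP1), with TAT1 higher, and 5 of 18 beta-oxidation genes (ECI1, FAA2, LPX1, POX1 and SPS19), with ANT1 higher. So were 3 of 71 ribosome biogenesis genes (UTP5, BFR2 and NHP2), while cytosolic ribosomal proteins had 3 lower (RPL18B, RPL8A and RPS26B) and 2 higher (RPL15B and RPS14B) of 128. Adjusted over the list alone the respiratory chain had 10 higher, the proteasome 9 higher and 1 lower, and a-specific genes 3 higher. Amino acid permeases had 5 lower and 1 higher, beta-oxidation 6 lower and 1 higher, and both ribosome lists 0 (limma; 11 of 71 and 20 of 128 at an unadjusted p under 0.05). With an estimated correlation these lists were lost, at adjusted p = 0.362 to adjusted p = 0.799, and the call of the cytosolic ribosomal proteins also ended after another quantile normalization (adjusted p = 0.442). With median-centred arrays 8 cytosolic ribosomal proteins were lower, and fewer respiratory chain and proteasome genes were higher.

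In N-lim snf1Δtor1Δ differed from snf1Δ in SPL2, which fell by 2.92 ± 0.26, from 6.09 to 3.17 (adjusted p = 1.7e-06, limma), SUL1, by -1.84 ± 0.19, PDC6, by -1.44 ± 0.15, and RSB1, at least 3.29-fold lower. The oxidoreductase gene OYE3 rose by 1.23 ± 0.16, NCA3 by 1.19 ± 0.30 and PRM6 by 0.94 ± 0.12. Of 14 Pho4 targets 4 fell, SPL2, PHO84 by -0.76 ± 0.13, PHO5 and VTC1 (8 adjusted over the list alone, and 8 with median-centred arrays), and the call held both ways (camera adjusted p = 1.82e-08; adjusted p = 0.0387 with an estimated correlation). In total 578 genes changed, 409 higher and 169 lower, of which 4 (OYE3, NCA3, ECM34 and YHL042W) and 11 changed at least 2-fold, and with median-centred arrays the split turned to 167 and 271. The count was 366, 241 and 323 without snf1Δ replicates 09, 10 and 11, and 324 without snf1Δtor1Δ replicate 01.

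Camera also called 10 lists in this comparison that were lost with an estimated correlation, at adjusted p = 0.343 to adjusted p = 0.534. Lower were 11 of 44 Gcn4 targets (16 adjusted over the list alone), LEU2 by -0.55 ± 0.07, and 12 of 66 mitochondrial ribosome genes (14 adjusted over the list alone). So were 5 nitrogen catabolite repression targets of 25, OPT2 by -1.38 ± 0.12, CPS1, GLN1, PUT1 and PUT4 (6 adjusted over the list alone). Stress genes had 5 of 25 lower, ALD3, CTT1, FMP45, HSP12 and TMA10 (10 lower and 1 higher adjusted over the list alone), and cytosolic ribosomal proteins 5 of 128, RPL12A, RPL17B, RPS0B, RPS9A and RPS9B (1 adjusted over the list alone). Lower too were 3 sulfate genes of 23 (SUL1, MET28 and CYS4) and 3 glycolysis genes of 20 (PDC6, HXK1 by -0.86 ± 0.08 and ENO1). The last were 2 vacuolar hydrolases of 10 (CPS1 and APE4) and 1 selection marker gene of 6 (LEU2). Higher were 7 of 33 proteasome genes (15 adjusted over the list alone). The vacuolar and marker calls ended after another quantile normalization (adjusted p = 0.147 and adjusted p = 0.0818). After it, fewer nitrogen catabolite repression and cytosolic ribosomal protein genes were lower. With median-centred arrays 13 cytosolic ribosomal proteins and 8 stress genes were lower, more glycolysis genes were lower, and fewer proteasome genes higher.

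Against tor1Δ, snf1Δtor1Δ showed what the SNF1 deletion adds in cells without TOR1. In C-lim PHO84 rose by 6.32 ± 0.13 (adjusted p = 3.7e-17, limma), EEB1 by 4.48 ± 0.09 and PHO5 at least 8.85-fold, and ADH2 fell at least 1110-fold, RGI2 at least 503-fold and FDH1 at least 479-fold. All 7 a-specific genes rose, BAR1 by 2.66 ± 0.10, and held both ways (camera adjusted p = 6.95e-06; adjusted p = 0.0338 with an estimated correlation). All 25 stress genes fell (camera adjusted p = 2.85e-20; adjusted p = 0.2 with an estimated correlation). Of 44 Gcn4 targets 31 rose and LEU4 fell (32 and 1 adjusted over the list alone), and of 66 mitochondrial ribosome genes 56 rose and MRP20 and MRP8 fell (57 and 2 adjusted over the list alone). Of 19 Cat8 and Adr1 targets 12 fell and CRC1, ICL1, PCK1 and YAT1 rose (13 and 5 adjusted over the list alone). All 3 lists were lost with an estimated correlation (adjusted p = 0.452, adjusted p = 0.431 and adjusted p = 0.222). In total 3049 genes changed, 2031 higher and 1018 lower, of which 159 and 287 changed at least 2-fold, and 17 lists were called by camera, 8 higher and 9 lower, of which the a-specific genes alone held and 16 were lost with an estimated correlation, at adjusted p = 0.2 to adjusted p = 0.535. Among them glycolysis, with 8 lower of 20 and PDC5, PFK1 and PYK2 higher, was called lower (adjusted p = 0.535 with an estimated correlation), but after another quantile normalization 6 were higher and 5 lower (adjusted p = 0.143).

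In N-lim PHO84 rose by 4.68 ± 0.13 against tor1Δ (adjusted p = 2.5e-14, limma), PHO5 at least 7.47-fold and PRM10 by 3.46 ± 0.14, while RSB1 fell at least 13-fold, MLS1 by -2.29 ± 0.15 and GPH1 by -2.21 ± 0.14. Of 37 respiratory chain genes 34 fell, SDH2 by -0.87 ± 0.07 (camera adjusted p = 6.28e-23; adjusted p = 0.00562 with an estimated correlation). Of 15 TCA cycle genes 14 fell (camera adjusted p = 3.32e-13; adjusted p = 0.0249 with an estimated correlation), so both lists held. Nitrogen catabolite repression targets had 15 lower of 25 and GDH2 and MEP1 higher, DAL80 by -0.84 ± 0.12 and DAL4 by -0.92 ± 0.17 (18 and 3 adjusted over the list alone; adjusted p = 0.416 with an estimated correlation). Thiamine and pyridoxine genes had 6 higher of 10, THI4 by 1.67 ± 0.17 (7 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation). In total 1828 genes changed, 1183 higher and 645 lower, of which 75 and 44 changed at least 2-fold, with a split of 800 and 882 with median-centred arrays. Of the 14 lists called, only the respiratory chain and TCA cycle held, and the others were lost with an estimated correlation, at adjusted p = 0.245 to adjusted p = 0.768. Among these, the call of the cytosolic ribosomal proteins, with 4 lower (RPL19A, RPL21B, RPS0B and RPS27A) and 2 higher (RPS17B and RPS22B) of 128, ended after another quantile normalization, where 2 (RPS17B and RPS22B) were higher and 1 (RPS27A) lower (adjusted p = 0.837), while 10 were lower with median-centred arrays. The calls of phospholipid synthesis (adjusted p = 0.121), vacuolar hydrolases, glycolysis and histones (adjusted p = 0.183 for each) ended there too, and that of vacuolar hydrolases also with median-centred arrays (adjusted p = 0.0564).

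Whether the effects of both deletions add up was tested as a genetic interaction, the TOR1 deletion effect in snf1Δ minus that in the reference strain. In C-lim it was positive for PCK1 at 2.17 ± 0.19 (adjusted p = 2.3e-06, limma), HXT4 at 1.93 ± 0.33 and FBP1 at 1.82 ± 0.21. It was negative for FIT3 at -2.74 ± 0.45 and FIT2 at -2.73 ± 0.46. STL1 and HXT1 were negative too, but lay at the floor in snf1Δtor1Δ, and HXT1 also in the reference and tor1Δ, so no size is given. Of 18 iron uptake genes 11 were negative (13 adjusted over the list alone; camera adjusted p = 1.39e-09; adjusted p = 0.444 with an estimated correlation). Of 20 glycolysis genes 6 were negative, ADH1 by -0.39 ± 0.05 (11 adjusted over the list alone; camera adjusted p = 2.2e-08; adjusted p = 0.444 with an estimated correlation). In total 313 genes deviated from additivity, 157 positive and 156 negative, of which 36 and 34 did so at least 2-fold, and 12 lists were called by camera, 0 with an estimated correlation and 6 by fry. The camera call of cytosolic ribosomal proteins ended after another quantile normalization (adjusted p = 0.0654). The count was 571 without reference replicate 10, 196 without snf1Δtor1Δ replicate 01, and 140 in a fit of only the 12 arrays of the comparison.

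In N-lim the genetic interaction was negative for PHO84 at -1.995 ± 0.19 (adjusted p = 1.35e-05, limma) and OPT2 at -0.83 ± 0.17. It was also negative for SPL2, at the floor in the reference and tor1Δ, and RSB1, at the floor in snf1Δtor1Δ, so no size is given. It was positive for the pheromone-regulated genes PRM6 at 1.66 ± 0.17, PRM5 at 1.19 ± 0.21 and PRM3 at 0.97 ± 0.15. Of 14 Pho4 targets SPL2 and PHO84 passed (5 adjusted over the list alone), and the list was lower both ways (camera adjusted p = 3.27e-10; adjusted p = 0.0141 with an estimated correlation). The median of the 128 cytosolic ribosomal protein genes was -0.136 with 0 members past limma over all genes or over the list alone and 29 at an unadjusted p under 0.05 (camera adjusted p = 2.4e-36; adjusted p = 0.252 with an estimated correlation). Camera called 16 lists, of which the Pho4 list held with an estimated correlation, and fry called 4. The autophagy and marker calls ended after another quantile normalization (adjusted p = 0.0981 and adjusted p = 0.149), and those of RNA polymerases and the proteasome with median-centred arrays (adjusted p = 0.0585 and adjusted p = 0.163). In total 38 genes deviated, 32 positive and 6 negative, of which 3 (PRM5, PRM6 and YPL113C) and 3 (SPL2, PHO84 and RSB1) did so at least 2-fold, and with median-centred arrays the split was 10 and 9. The count was 18 after another quantile normalization, 23 with dim genes left out, 15 without snf1Δ replicate 10, 20 and 22 without reference replicates 10 and 11, 20 without tor1Δ replicate 11 and 23 without snf1Δtor1Δ replicate 01.

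**Figure D3:**
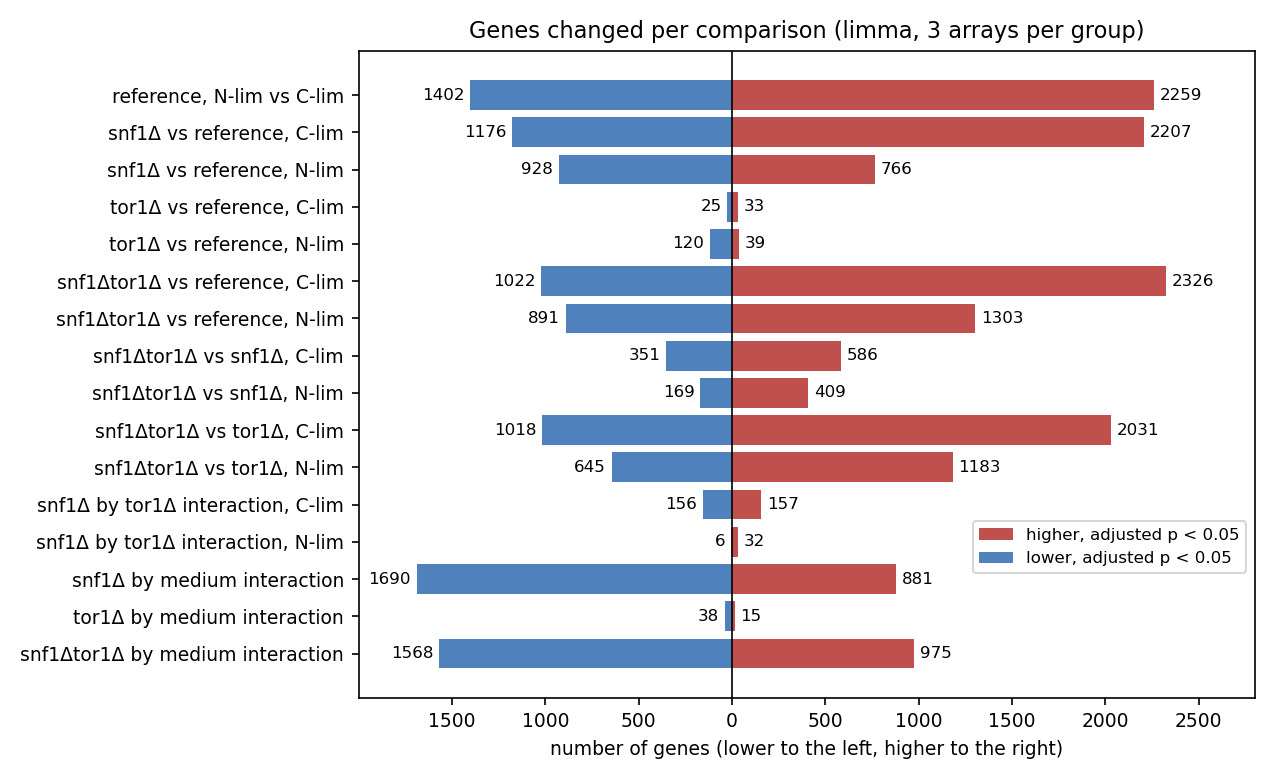
Number of genes (horizontal axis) higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in each of the 16 comparisons (vertical axis). The SNF1 deletion in C-lim changed 3383 genes, 2207 of them higher, and the TOR1 deletion in C-lim 58.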

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

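The results below stand out because the effect of a deletion differed between groups by a test of the difference, or because a signal lay in probe sets that the report's comparisons leave out. Of the tests below, 2 were written after the results were seen, the test for alpha cells and the correlation without shared arrays.

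In C-lim, the effect of the TOR1 deletion with and without SNF1 differed for 313 genes (limma, adjusted p under 0.05) and 12 lists by camera, of which 0 held with an estimated correlation. As fitted, the positive differences included PCK1 2.172, HXT4 1.929, FBP1 1.819, PHM8 1.783 and YHL042W 1.667, and the negative ones STL1 -3.63, RGI2 -3.019, HXT1 -2.993, FIT3 -2.743 and FIT2 -2.731. In N-lim 38 genes and 16 lists differed, of which 1 list held with an estimated correlation, with PRM6 1.659, YPL113C 1.218, PRM5 1.19, AFB1 0.979 and PRM3 0.966 against SPL2 -2.828, PHO84 -1.995, RSB1 -1.657, OPT2 -0.83 and HXK1 -0.47. Of 100 splits of the arrays, 9 in C-lim and 11 in N-lim gave as many genes. Such splits can carry the effects of the deletions themselves, so they cannot decide whether chance gave these counts. STL1, RGI2, HXT1 and YHL042W in C-lim and SPL2 and RSB1 in N-lim lay at the floor in at least 1 of the 4 groups, so their values and rank are limited by it.

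The effect of the SNF1 deletion differed between N-lim and C-lim for 2571 genes and 20 lists, of which 2 lists held with an estimated correlation, with GRE1 8.656, YDL218W 8.591, SPS100 7.662, ADY2 6.988 and FDH1 6.91 against YGR035C -6.215, PTR2 -4.909, SIT1 -4.696, EEB1 -4.671 and YJL213W -4.426. That of the TOR1 deletion differed for 53 genes and 15 lists, of which 0 lists held with an estimated correlation (camera), with DAL4 1.582, PHO84 1.465, BIO5 1.189, OYE3 1.021 and YHL042W 0.907 against SUL1 -2.234, CDA1 -1.84, ISF1 -1.681, SPS4 -1.383 and ARO10 -1.366. That of losing both kinases differed for 2543 genes and 18 lists, of which 2 lists held, with RGI2 9.335, ADH2 8.868, FDH1 8.742, YDL218W 8.59 and ADY2 8.359 against YGR035C -6.465, YGR109W-A -5.13, PTR2 -5.033, EEB1 -4.951 and YJL213W -4.323. YDL218W, ADY2, FDH1, RGI2, BIO5, ADH2, CDA1, YHL042W and YGR109W-A lay at the floor in at least 1 of the groups compared, so their values and rank are limited by the floor.

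Among the 218 probe sets without a gene name, limma found 67 higher and 68 lower in snf1Δ than in the reference in C-lim, 32 and 42 in N-lim, 89 and 55 in snf1Δtor1Δ in C-lim and 50 and 42 in N-lim. In tor1Δ 0 were higher and 2 lower in C-lim and 0 higher and 6 lower in N-lim (31 and 34 at an unadjusted p under 0.05). The share of higher ones in snf1Δ in C-lim, 30.7%, lies below the 40.5% of the named genes, while the other shares were near those of named genes, 14.7% and 14.1% in N-lim, and 40.8% and 42.7%, then 22.9% and 23.9%, in snf1Δtor1Δ in C-lim and N-lim. What these probe sets measure is not given in the sources used here.

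The first pattern weighed is the rise of MF(ALPHA)1, by 7.37, together with all 7 a-specific genes in the reference strain in N-lim. Alpha cells in the N-lim cultures would raise the other alpha-specific genes too, but STE3 changed by -0.583, and MF(ALPHA)2 stayed at the floor, which speaks against that explanation, although SAG1 rose from 6.05 to 7.33. The scaling of the arrays does not make the rise, since MF(ALPHA)1 changed by 7.259 under the lower of the other scalings. A biological explanation was not tested.

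The second pattern is that the SNF1 deletion in C-lim moved genes along the difference between N-lim and C-lim. Reference arrays common to both comparisons would make such a correlation, but with the medium difference taken from tor1Δ arrays alone it was r = 0.687 over 5449 genes, which are not independent, and 0.685 after another quantile normalization, which speaks against shared arrays and scaling. In N-lim the correlation was -0.0833. A candidate explanation is that cells without SNF1 may carry part of the state of glucose-sufficient cells in C-lim, for which no test was run.

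The third pattern is the lower level of iron uptake genes in snf1Δtor1Δ than in snf1Δ in C-lim, where 13 of 18 fell. With each array left out in turn at least 11 fell, and under the other scalings at least 14, which speaks against 1 array or the scaling as the cause. The strains share 0 culture numbers in C-lim, so a separate series of cultures, which might differ in iron supply, could not be told apart from an effect of the TOR1 deletion.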

How the results depend on the processing

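Alternatives added after the data were seen are leaving out the genes at the floor, the replicate block in a fit of only the arrays of the comparison, and median-centred arrays for the lists. The number of arrays limits all counts, and no test of the cause was made where a count moved, except that the stricter settings hold fewer genes by construction. Signal at the floor limits what can be seen of low genes.

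With at least 2-fold added to the threshold, the counts were 757 for the reference in N-lim against C-lim, 512 and 129 for snf1Δ in C-lim and N-lim, 3 and 13 for tor1Δ, 486 and 145 for snf1Δtor1Δ, 56 and 15 for it against snf1Δ, 446 and 119 against tor1Δ, 70 and 6 for the genetic interaction, and 505, 13 and 530 for the interactions of snf1Δ, tor1Δ and snf1Δtor1Δ with the medium. With an estimated correlation the lists called by camera were, in the same order, 2, then 0 and 3, 0 and 1, 1 and 2, 0 and 1, 1 and 2, 0 and 1, and last 2, 0 and 2. With fry they moved to 33 for snf1Δ in C-lim, 7 for tor1Δ in N-lim, 27 and 26 for snf1Δtor1Δ, 6 for it against snf1Δ in N-lim, 27 against tor1Δ in C-lim, 6 and 4 for the genetic interaction and 4 for tor1Δ with the medium.

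The genetic interaction in N-lim, 38 genes, moved to 18 after another quantile normalization, 19 with median-centred arrays and 23 without dim genes. In fits of only the arrays of the comparison, tor1Δ moved to 2 in C-lim and 67 in N-lim, snf1Δtor1Δ against snf1Δ in C-lim to 401, the genetic interaction in C-lim to 140 and tor1Δ with the medium to 31. All other counts stayed within 1.5 times under these settings, as did all counts without floor genes, with all probe sets, the mean of probe sets, or a trended and robust variance; the cause was not tested.

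With the replicate block, tor1Δ in C-lim moved to 8 genes and 4 lists and its interaction with the medium to 10 genes and 10 lists. The numbers may pair some arrays of that interaction, but 07 and 08 occur in tor1Δ C-lim alone, so the fixed block leaves 1 of its 3 arrays. The replicate block gave 3689 genes for the reference, 3147 and 1701 for snf1Δ, 116 for tor1Δ in N-lim, and 2374 and 2547 for the interactions of snf1Δ and snf1Δtor1Δ with the medium, and 13 lists for tor1Δ in N-lim. Of 539 named values under the block, 44 were no longer past the threshold and 1 was newly past it, mostly for tor1Δ. The block moved no other count of genes or lists by over 1.5 times. No paired analysis with a fixed block was possible for 8 comparisons because snf1Δtor1Δ shares no number with other strains. A random block kept all counts within 1.5 times.

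Leaving out each array in turn gave 3458 to 3581 genes for the reference, 3143 to 3418 for snf1Δ in C-lim, 1332 to 1481 for snf1Δ in N-lim, 21 to 184 for tor1Δ in C-lim, 86 to 114 for tor1Δ in N-lim, 3122 to 3339 for snf1Δtor1Δ in C-lim, 1878 to 2096 for snf1Δtor1Δ in N-lim, 517 to 972 for it against snf1Δ in C-lim, 241 to 525 for the same in N-lim, 2723 to 3004 for it against tor1Δ in C-lim, 1518 to 1713 for the same in N-lim, 196 to 571 for the genetic interaction in C-lim, 15 to 39 for that in N-lim, 2373 to 2670 for snf1Δ with the medium, 24 to 86 for tor1Δ with the medium, 2368 to 2607 for snf1Δtor1Δ with the medium. The lists called for tor1Δ in C-lim went from 5 to 13.

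Of 17070 values of named genes under all alternatives, 16222 kept their direction and side of the threshold, 821 were no longer past it, 27 were newly past it and 0 reversed.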

Other observations

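Splits within arrays of equal SNF1 status and splits that part as many pairs were added after the first results of the splits were seen. The 4 lists below were called by camera in no comparison. Of the 14 hexose transporters and sensors measured, 4 (HXT1, HXT3, HXT4 and RGT2) rose and 4 (HXT2, HXT5, HXT7 and SNF3) fell in the reference in N-lim against C-lim (camera adjusted p = 0.631), since single transporters went opposite ways. HXT2 and HXT3, picked here after their values were seen, were lower by -7.39 ± 0.25 (SE, n = 3) and higher by 4.42 ± 0.19 (limma). With the SNF1 deletion HXT2 changed by -1.10 ± 0.25 in C-lim and 2.16 ± 0.25 in N-lim, an interaction of 3.26 ± 0.36.

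Fatty acid synthesis had 6 higher and 3 lower genes (FAA4, FAS1 and OLE1) of 10 in the reference in N-lim (camera adjusted p = 0.361), purine and one-carbon genes 9 higher and 0 lower of 13 (camera adjusted p = 0.0998), and flocculins 0 higher and 1 lower (FLO11) of 4 (camera adjusted p = 0.676).

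Each comparison of 3 against 3 arrays was repeated on all 10 splits of its arrays, which are too few for a share under 0.05. The real split was the highest in every case, 1 of 10. The genes at an adjusted p under 0.05 (limma) in the real split and in the highest other split were 3661 and 0 for the reference in N-lim against C-lim, 3383 and 4 for snf1Δ in C-lim, 1694 and 0 in N-lim, 58 and 39 for tor1Δ in C-lim, and 159 and 0 in N-lim. They were 3348 and 1 for snf1Δtor1Δ in C-lim, 2194 and 1 in N-lim, 937 and 7 against snf1Δ in C-lim, 578 and 3 in N-lim, 3049 and 0 against tor1Δ in C-lim, and 1828 and 10 in N-lim.

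The interactions were set against 100 splits of their 12 arrays. For the genetic interaction, 9 of 100 splits in C-lim gave as many genes as the real 313, with a highest other count of 2865, and 11 of 100 in N-lim gave as many as 38, with a highest other count of 892. Splits that line up with a deletion carry its effect, and counts several times the real one point to this. These splits therefore cannot decide whether chance gave the real counts. Splits within arrays of equal SNF1 status do not decide the question either. In each medium 6 of them besides the real one gave as many genes, and all 6 keep snf1Δ and snf1Δtor1Δ apart, so they carry the effect of the TOR1 deletion in cells without SNF1. Among splits that mix these 2 strains, the highest count was 26 in C-lim and 13 in N-lim (limma), but mixing also puts the deletion effect into the spread within groups.

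For the interactions with the medium, 3 of 100 splits reached the real count for snf1Δ (2571, highest other 2623), 2 for tor1Δ (53, highest other 146) and 1 for snf1Δtor1Δ (2543, highest other 2508), each a share under 0.05 if all arrays are taken as independent. These shares do not decide about chance. A split that swaps the strains in a single medium carries the deletion effects of both media. A split that mixes the strains puts the deletion effect into the spread within groups. The replicate numbers pair some of these arrays, and only 10 splits part as many pairs as the real one, too few for a share under 0.05. The highest other count among them was 0 for snf1Δ, 4 for tor1Δ and 0 for snf1Δtor1Δ (limma).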
